A study of Rattus norvegicus with 6 samples.

How the data were processed

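Total RNA from liver tissue blocks of 6 rats was measured on 6 Agilent arrays, 1 array per animal, per the labels. The groups were 3 normal livers and 3 fibrotic livers from rats whose bile duct had been tied off (bile duct ligation, which blocks bile flow and scars the liver). The labels name the tissue of each array, and the design text gives 3 rats per group. The sex of the animals is not given in the sources used here. Replicates were numbered within each group in the order of the records, so a number names an array and never pairs arrays.

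Labelled cDNA was hybridised in 1 colour (Cy3), per the labels' protocols. The deposited values are spot intensities on a linear scale that Agilent Feature Extraction 11.5.1.1 wrote for each array, with background subtracted, trends across the array removed and negative values replaced by small positive ones in the processed signal column, per the file headers. No normalization between arrays is recorded in these files. All 6 arrays lay on 1 slide and in 1 scan, so slide and scan could not be separated further. The first row of the slide held the 3 normal arrays and fibrosis array 1, and the second row held fibrosis arrays 2 and 3.

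Each array held 58717 spots other than controls, for 30367 probes. Accessions in the files were matched without version numbers to the RefSeq gene table of the GRCr8 assembly, which named 18355 probes and 15443 genes and left 12012 probes without a symbol. No coordinates were taken from that table.

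The processed signals were put on the log2 scale and each array's 75th percentile was subtracted. Control spots were left out, and so were spots that the scanner software marked as non-uniform or as population outliers, called marked spots here. Saturated spots would have been kept, and there were 0. Spots of 1 probe were averaged. A probe was tested if it was well above background on all arrays of at least 1 group, with at least 0.5 of its spots called so, and had a value on at least 2 arrays of each group. For a gene with several probes, the probe with the highest mean over the 6 arrays stood for it. Of 721 genes with more than 1 tested probe, 543 had all probes on one side of 0. Rasl12 had probes called in opposite directions, at 2.06 and -1.96.

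Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. Values are log2 differences, fibrosis minus normal, with their standard error. Where a probe was not well above background on any array of a group, its fold is a lower bound. The bound applies to the processed signals, and values with another background correction can lie below it. The bright group's mean was set against the dim group's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background. All 3 arrays of the brighter group measured each such probe above background, and genes with a bound from fewer unmarked arrays are named.

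There were 30 gene lists (pathways, and markers of cell types a liver block could hold). Lists with at least 5 tested members were tested against all other genes with camera at a preset correlation between genes of 0.01, with adjustment over lists. Beside it, camera was run with a correlation estimated for each list, called an estimated correlation here. That setting also tests with far fewer degrees of freedom, so calls it ends can come from either change. The fry test of limma asks whether the genes of a list move one way on balance. It was run on genes with a value on every array. Counts of called members are given over all genes tested and adjusted over the list alone.

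The genes named in the text follow a rule. It takes the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap. It adds 12 fixed genes and, for each list, up to 2 called members with the largest increase and up to 2 with the largest decrease. Where under 2 members are called, the members with the smallest p complete the pair. The tests, lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

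Leaving out marked spots removed many bright spots, and 3426 genes that were above background then had too few arrays. The alternative that kept the marked spots was therefore used beside the main values for those genes, and genes that only it tested are said to be measured with marked spots kept. Which of its genes to name was decided after seeing the data, with the same rule.

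Other alternatives were quantile normalization, the array median and cyclic loess in place of the 75th percentile, no filter on dim probes, a filter on all 6 arrays, the mean or the lowest probe of a gene, eBayes with trend and robust settings, array weights, stricter thresholds, and leaving out each array in turn. Background correction by normexp on mean signals was not run, since the files used here hold no such column. Normexp with an offset of 50 on median signals, scaling to the 8 E1A spike-in control probes, slide row as a block, marked spots kept with quantile normalization, and every alternative repeated with marked spots kept were chosen after seeing the data. Slide row as a block sets fibrosis array 1 alone against the normal arrays, so it rests on 1 fibrotic liver.

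The test was checked on simulated data of 7433 genes with 200 changed genes for fibrosis against normal. It recovered 2% of genes changed by a log2 of 0.5, 10% at 1, 72% at 2 and 78% at 3, with 3.57% false calls. In the data far more genes, 1781, were called, so these shares need not hold there. The simulated noise was drawn once, independently between genes, with the same SD in both groups. In the data the median SD was 0.240 among normal and 0.441 among fibrotic livers. The number of arrays, 3 per group, limits the precision. Figures were drawn with matplotlib 3.10.9.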

Results

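Gene expression was measured in the livers of 3 normal rats and of 3 rats with hepatic fibrosis after bile duct ligation, an operation that blocks bile flow, with 1 array per animal. The comparison asks how gene expression in fibrotic liver tissue differed from that in normal liver. The 75th percentile of the processed signal was 4016 ± 330 (SD, n = 3) on the normal arrays and 5453 ± 833 (SD, n = 3) on the fibrosis arrays, and the share of spots well above background was 68.8% ± 1.45 (SD, n = 3) and 72.8% ± 4.70 (SD, n = 3). The number of arrays limits the precision of every value.

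Fibrotic and normal livers stood apart on the arrays, and the fibrotic livers differed more among themselves. Across 5500 genes with a value on every array, Pearson correlations between arrays ran from 0.978 to 0.986 among normal livers, from 0.925 to 0.959 among fibrotic livers, and from 0.844 to 0.889 between the groups. These correlations are across genes, which are not independent replicates. The first principal component held 71.5% of the variance and the second 14.2%. The median SD of a gene was 0.240 among normal livers and 0.441 among fibrotic livers on the log2 scale.

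Of 7433 genes tested, 1352 were higher in fibrosis and 429 were lower, of which 1274 and 338 changed at least 2-fold. The genes with the largest increases included Scara3 (a scavenger receptor), Msln (mesothelin, a surface protein of mesothelium), Cldn9 (a claudin of tight junctions), Ccl20 (a chemokine) and Rhbdl2 (a rhomboid protease). Scara3 rose at least 68.6-fold, Cldn9 at least 48.8-fold on 2 unmarked fibrosis arrays, Ccl20 at least 38.7-fold and Rhbdl2 at least 33.0-fold, since none of these was well above background in normal liver. Msln rose by a log2 of 7.77 ± 0.52 (limma adjusted p = 9.94e-05) and was above background on 1 of the normal arrays. The other top increases were Uchl1 (at least 27.0-fold), Cdhr5 (at least 34.3-fold, 2 unmarked fibrosis arrays), Matn4 (at least 36.8-fold, 2 unmarked fibrosis arrays), Cox6a2 (at least 30.8-fold) and Vtcn1 (at least 17.8-fold), with adjusted p between 8.82e-06 and 9.94e-05 over the 10 genes. With normexp background correction the log2 values of the 9 genes other than Msln lay between 3.48 (Vtcn1) and 5.21 (Scara3), against 6.15 and 7.85, and all 9 stayed called. The normexp values of Vtcn1 and Scara3 are smaller than their bounds, so the bounds hold for the processed signals only.

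The largest decrease was that of Cyp2c11, the main cytochrome P450 of male rat liver, at -7.20 ± 0.68 (adjusted p = 0.000396, 2 unmarked normal arrays), a 147-fold change. Inmt, an amine methyltransferase, fell by 6.85 on the log2 scale (SE 0.66, adjusted p = 0.000241). Prlr, the prolactin receptor, changed by -3.81 ± 0.53, Nox4, an NADPH oxidase, by -3.85 ± 0.47, and Paqr9 by -3.89 ± 0.35. Lhx8 (at least 19.5-fold), Plppr1 (at least 6.64-fold), A1bg (at least 6.6-fold) and Prss32 (at least 4.95-fold) were not well above background on any fibrosis array. With normexp these decreases were smaller, at -2.07 for Plppr1, -2.16 for Prss32, -2.24 for A1bg and -2.09 for Nox4, and these 4 stayed called. Those of Plppr1, Prss32 and A1bg were then smaller than the bounds given. Mmd2 changed by -4.36 ± 1.07 (adjusted p = 0.0208). Its call was lost without fibrosis array 1 (-3.92, adjusted p = 0.0611) or fibrosis array 3 (-3.91, adjusted p = 0.0574).

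The groups did not overlap in 2295 of the 5500 genes with a value on all 6 arrays, where chance gives 10%, and 2655 of all tested genes had an unadjusted p under 0.05. The balance of higher and lower genes depended on the scaling. Higher and lower genes numbered 1002 and 677 with quantile normalization, 1005 and 1170 with the array median, and 1588 and 108 with scaling to E1A control probes. The median log2 difference of all genes was 0.03 in the main setting, -0.13 with quantile normalization, -0.33 with the array median and 0.38 with E1A scaling, and changes are relative to these. With marked spots kept, 10864 genes were tested and 1720 were higher and 991 lower. With quantile normalization as well, 1351 were higher and 1035 lower, so the scaling mattered here too. Of the 1781 genes called without marked spots, 1718 were called again in the same direction when they were kept. The lower genes numbered 189 without normal array 1, 210 without normal array 2 and 142 without normal array 3, and the higher genes 889 without normal array 3.

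Among the 12 genes fixed beforehand, markers of scarring and bile duct cells were higher and bile acid carriers lower. Spp1 (osteopontin) rose by 4.81 ± 0.49 (adjusted p = 0.000576, 2 unmarked fibrosis arrays), Col1a1 (type I collagen) by 2.09 ± 0.55 (0.0279), Acta2 (smooth muscle actin of myofibroblasts) by 2.03 ± 0.54 (0.0282) and Tgfb1 by 1.6 ± 0.30 (0.00897, 2 unmarked fibrosis arrays). When marked spots were kept, Krt19 (a bile duct keratin) rose by 3.49 ± 0.24 (adjusted p = 6.21e-05) and Timp1 (an inhibitor of matrix proteases) by 2.42 ± 0.26 (0.000380). Slc10a1, the bile acid uptake carrier of hepatocytes, then fell by 1.42 (SE 0.27, adjusted p = 0.00681) and Abcb11, the bile salt export pump, fell by 1.06 (SE 0.23, 0.0127). Col3a1 at 1.27 ± 0.44 (0.0715), Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.49 ± 0.48 (0.0530) and Alb (albumin) at -0.84 ± 0.37 (0.136) did not pass the test. Col3a1 passed without fibrosis array 3 (1.67, 0.0213), Cyp7a1 without normal array 2 (2.02, 0.0118) and Alb without fibrosis array 2 (-1.16, 0.0466).

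Several of these calls were lost with another scaling or when 1 array was left out, which also leaves fewer arrays for the test. The values given here kept their direction. The call of Acta2 was lost without normal array 2 (2.04, adjusted p = 0.0748) or 3 (1.81, 0.0947) and with quantile normalization (1.69, 0.0718). That of Col1a1 was lost without normal array 2 (2.11, 0.0723) or 3 (1.90, 0.0917), without fibrosis array 1 (1.82, 0.0825) or 2 (1.66, 0.0780) and with quantile normalization (1.85, 0.0527), and its value was 3.19 with marked spots kept. Abcb11 lost its call without normal array 1 (-1.01, 0.0532) or 3 (-1.05, 0.0647), with cyclic loess (-0.79, 0.0524) and with E1A scaling (-0.71, 0.206), and Slc10a1 with E1A scaling (-1.08, 0.0806).

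**Figure D1:**
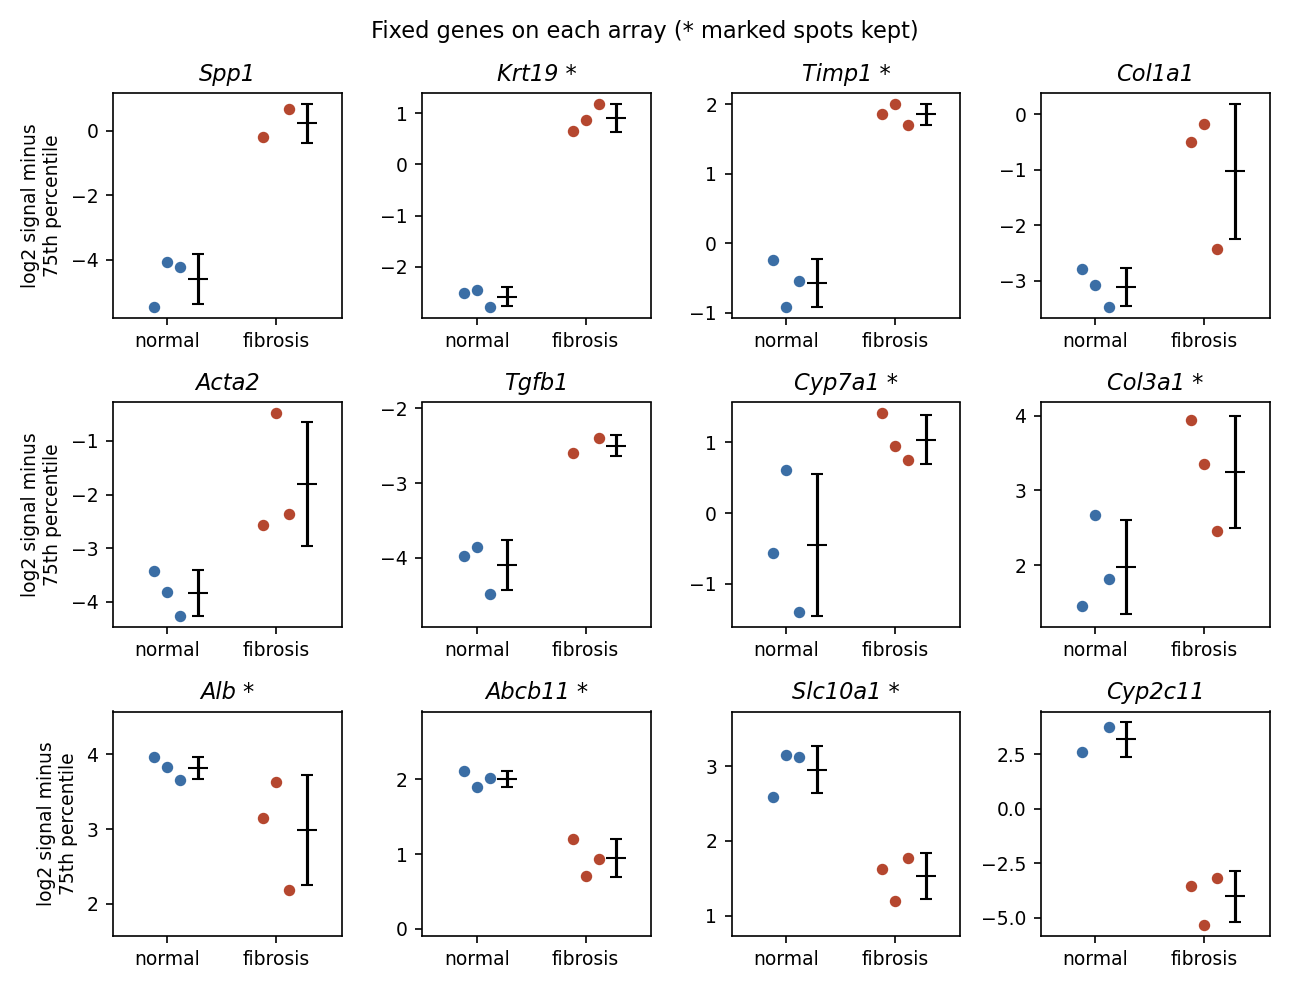
Normalised log2 intensity (log2 processed signal minus the array's 75th percentile, vertical axis) of the 12 fixed genes on each array, with the group mean and SD (n = 3, or 2 where an array had only marked spots) and an asterisk where spots that the scanner software marked non-uniform or outlying were kept. Spp1 rose by 4.81 and Cyp2c11 fell by 7.20, while Alb differed by -0.84, which did not pass the test.

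Genes of the extracellular matrix rose together. Of 8 collagen genes tested, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with Col15a1 at 3.56 ± 0.54 (adjusted p = 0.00221) and Col8a1 at 3.48 ± 0.44 (0.000930). Of 12 other matrix genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), among them Vcan (versican), at least 14.1-fold, and Eln (elastin) at 3.38 ± 0.45 (0.00115), whose probe of lowest signal gave 0.58 (0.339). Of 15 genes that remodel or crosslink matrix, 10 rose and 1 fell (11 and 1 adjusted over the list alone). Loxl1, a lysyl oxidase that crosslinks elastin, rose by 4.75 ± 0.28 (6.17e-05, 2 unmarked fibrosis arrays) and, with marked spots kept, Mmp12 (a macrophage elastase) by 6.29 ± 0.41 (4.43e-05). The list medians were 1.83, 1.40 and 1.82, with camera adjusted p of 0.000718, 0.00125 and 0.000170, and all 3 calls were lost with an estimated correlation (adjusted p = 0.216 with an estimated correlation for each).

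Markers of stellate cells and myofibroblasts, the cells that lay down scar matrix, were also higher. Of 12 tested, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 1.59 (camera adjusted p = 0.00476; adjusted p = 0.328 with an estimated correlation). Vim (vimentin) rose by 3.12 ± 0.30 (adjusted p = 0.000444, 2 unmarked fibrosis arrays), Cygb (cytoglobin) by 2.99 ± 0.40 (0.00125) and, with marked spots kept, Des (desmin) by 3.01 ± 0.28 (0.000198). The call of the list was lost without fibrosis array 1 (1.02, 0.0741) or fibrosis array 2 (0.66, 0.187), and with fry the adjusted p lay just over 0.05. Its median was 1.33 over 19 genes with marked spots kept (2.65e-05; adjusted p = 0.142 with an estimated correlation).

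Of 10 genes of TGF-beta and PDGF signalling, 4 rose and 0 fell (4 and 1 adjusted over the list alone), and the list did not pass (median 0.29, camera adjusted p = 0.377), its median turning to -0.06 with the array median, -0.03 for the lowest probe of each gene and -0.20 without fibrosis array 1. It passed with no filter on dim probes (0.53, 0.0493). Among values with marked spots kept, 9 of 20 rose and 1 fell (10 and 2 adjusted over the list alone) at a median of 0.89 (0.00157; adjusted p = 0.114 with an estimated correlation), a median that the array median scaling moved to 0.54 and the lowest probe of each gene to 0.54. Itgb6, an integrin subunit that activates latent TGF-beta, rose by 5.02 ± 0.34 (5.28e-05) and Ccn2 (connective tissue growth factor) by 4.30 ± 0.43 (0.000295), both with marked spots kept. Tgfb2 stood at 2.95 ± 0.36 (0.00132, 2 unmarked fibrosis arrays), but its probes differed: it was -0.62 for the lowest probe, 0.64 for the mean of its probes (0.310), -0.58 without fibrosis array 1 (0.219) and -0.57 without fibrosis array 3 (0.138).

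Markers of cholangiocytes, the cells that line bile ducts, rose most among the lists tested, with a median of 3.51, or 3.11 with genes at their bound (camera adjusted p = 4.44e-07; adjusted p = 0.216 with an estimated correlation). Of 13 tested, 11 rose and 0 fell (11 and 0 adjusted over the list alone), and with marked spots kept 18 of 21 rose and 0 fell (20 and 0 adjusted over the list alone). Dcdc2 rose at least 27.0-fold (4.43 on the log2 scale, or 21.5-fold, with marked spots kept, below that bound) and Cldn4, a claudin, by 5.20 ± 0.43 (adjusted p = 0.000117). Once marked spots were kept, the keratin Krt7 rose by 5.65 ± 0.53 (0.000202) and the secretin receptor Sctr by 5.47 ± 0.44 (9.91e-05). The list's median was 3.49 with marked spots kept (2.67e-13; adjusted p = 0.114 with an estimated correlation).

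Of 7 oncofetal and progenitor genes, 3 rose and 1 fell (the same numbers, 3 and 1, adjusted over the list alone), at a median of 1.22 that did not pass (camera adjusted p = 0.193) and was -0.01 without fibrosis array 2. H19, an imprinted non-coding RNA, rose by 5.67 ± 0.53 (adjusted p = 0.000394, 2 unmarked fibrosis arrays) and Gpc3 (glypican 3) by 3.00 ± 0.39 (0.00162, 2 unmarked fibrosis arrays), while Igf2, the growth factor imprinted together with H19, fell by 1.16 on the log2 scale (SE 0.26, 0.0147). The call of Igf2 was lost without normal array 2 (-0.95, 0.0611) and with E1A scaling (-0.82, 0.116). In values with marked spots kept, 6 of 10 rose and 1 fell (6 and 1 adjusted over the list alone). Their median was 1.26 (0.00309; adjusted p = 0.234 with an estimated correlation).

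Genes of bile acid handling were lower in part, and how many depended on the scaling. With marked spots kept, 10 of 15 genes of bile acid synthesis fell and 1 rose (12 and 2 adjusted over the list alone). Falls and rises numbered 4 and 2 with quantile normalization and with cyclic loess, 2 and 2 with E1A scaling and 12 and 1 with the array median. The median was -1.01 (camera adjusted p = 0.000513; adjusted p = 0.142 with an estimated correlation), or -0.63 with quantile normalization, -0.60 with cyclic loess and -0.67 with E1A scaling. Only 4 of them were tested without marked spots, too few for a list test, of which 1 rose and 1 fell (1 and 2 adjusted over the list alone). Cyp39a1, an oxysterol hydroxylase, fell by 2.29 on the log2 scale (SE 0.45, adjusted p = 0.00774, or -1.39 with normexp), and Cyp7b1 of the alternative synthesis pathway rose by 2.32 ± 0.39 (0.00367).

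Of 10 bile acid and organic anion transporters, 2 rose and 5 fell (2 and 6 adjusted over the list alone), and the list did not pass (median -0.91, camera adjusted p = 0.0710). It passed without fibrosis array 3 (-1.0, 0.0369), with E1A scaling (-0.58, 0.0239), normexp (-1.01, 0.0393), the trend and robust settings (-0.91, 0.0363) and the filter on all 6 arrays (0.00779), but not with quantile normalization (-0.76, 0.257), cyclic loess (-0.70, 0.158) or the array median (-1.29, 0.162). Abcc3, an exporter towards the blood, rose by 2.19 ± 0.50 (adjusted p = 0.0153) and Slc10a2, a bile acid uptake carrier of bile duct and gut epithelium, at least 1.85-fold (0.00456). With normexp Slc10a2 stood at 0.40 on the log2 scale, below that bound, and lost its call (limma adjusted p = 0.240). Abcb1a, a drug exporter, fell by 2.20 (SE 0.46, 0.0106, or -1.15 with normexp) and Abcg5, a sterol exporter, by -1.84 ± 0.31 (0.00577, 2 unmarked normal arrays). When marked spots were kept, 2 of 18 rose and 12 fell (2 and 12 adjusted over the list alone). The falls numbered 9 with quantile normalization, 8 with cyclic loess, 6 with E1A scaling and 12 with the array median. The list had a median of -1.04 (0.000896; adjusted p = 0.114 with an estimated correlation).

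Of 10 bile acid and xenobiotic receptors, 0 rose and 2 fell (0 and 2 adjusted over the list alone). The falls numbered 3 with quantile normalization, 2 with cyclic loess, 1 with E1A scaling and 4 with the array median. The median was -0.67 (camera adjusted p = 0.00440; adjusted p = 0.216 with an estimated correlation), which was -1.04 with the array median and -0.33 with E1A scaling. Nr0b2 (SHP, a repressor of bile acid synthesis) changed by -2.52 ± 0.48 (adjusted p = 0.00703). Ppara, a regulator of fatty acid oxidation, changed by -1.07 ± 0.23 (0.0118), and its call was lost without normal array 3 (-0.97, 0.0703) and with E1A scaling (-0.73, 0.158).

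Cytochrome P450 enzymes were lower as a list, though the number of genes that fell depended on the scaling. Of 10 cytochrome P450 genes tested, 0 rose and 6 fell (0 and 9 adjusted over the list alone). The median was -1.13 (camera adjusted p = 1.06e-05; adjusted p = 0.216 with an estimated correlation), and with marked spots kept 1 of 25 rose and 19 fell (1 and 21 adjusted over the list alone). The 6 falls became 3 with quantile normalization, cyclic loess or E1A scaling and 9 with the array median, and the 19 became 12, 11, 9 and 21 in this order. Beside Cyp2c11, Cyp2d3 changed by -2.18 ± 0.36 (adjusted p = 0.00463, 2 unmarked normal arrays) and, with marked spots kept, Cyp3a9 by -4.86 ± 0.57 (0.000641). Cyp2c12, the female-typical enzyme of rat liver, was the 1 that rose with marked spots kept, by 1.1 ± 0.31 (0.0330). Its call was lost without normal array 1 (0.92, 0.115) or 3 (0.96, 0.139), without fibrosis array 1 (1.03, 0.0899) or 3 (1.07, 0.0557), and with the array median (0.74, 0.0843) or no filter (0.0603).

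Conjugation enzymes went both ways. Of 5 tested, 1 rose and 2 fell (1 and 2 adjusted over the list alone), and the list did not pass (median -0.59, camera adjusted p = 0.0766). It passed with E1A scaling (-0.24, 0.0484), no filter (-0.83, 0.0197) and the trend and robust settings (-0.59, 0.0330), but not with quantile normalization (-0.27, 0.369), cyclic loess (-0.16, 0.309) or the array median (-1.0, 0.157). Among values with marked spots kept, 3 of 23 rose and 11 fell (3 and 16 adjusted over the list alone), and the falls numbered 6 with quantile normalization, 6 with cyclic loess, 5 with E1A scaling and 19 with the array median. The median stood at -0.89 (7.41e-05; adjusted p = 0.0732 with an estimated correlation), or -0.53 with quantile normalization, -0.48 with cyclic loess and -0.54 with E1A scaling. Ugt2b1, a glucuronosyltransferase, changed by -2.71 ± 0.32 (adjusted p = 0.00116, 2 unmarked normal arrays). Once marked spots were kept, Nat8, an acetyltransferase, changed by -4.34 ± 0.33 (8.93e-05), whereas Gstm3, a glutathione transferase, rose by 4.10 ± 0.34 (0.000115).

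Secreted proteins of hepatocytes were lower as a group. In values with marked spots kept, 0 of 32 rose and 11 fell (0 and 22 adjusted over the list alone). These falls numbered 4 with quantile normalization, 4 with cyclic loess, 3 with E1A scaling and 28 with the array median. The median was -0.78 (camera adjusted p = 2.31e-08; adjusted p = 0.0732 with an estimated correlation), with Apoa4 at -2.31 ± 0.50 (adjusted p = 0.0115) and Pon1 (paraoxonase) at -1.89 ± 0.28 (0.00207). Of 8 tested without marked spots, 0 rose and 1 fell (0 and 5 adjusted over the list alone), against 8 with the array median and 0 with the other 3 scalings. Together they had a median of -0.72 (0.00159; adjusted p = 0.216 with an estimated correlation). That call was lost with quantile normalization (-0.33, 0.155) and cyclic loess (-0.24, 0.154), and its median was -0.38 with E1A scaling. The medians with marked spots kept were -0.32 and -0.22 there, and -0.44 with E1A scaling.

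Amino acid and fatty acid breakdown were lower as groups. Of 8 urea cycle and amino acid genes, 0 rose and 4 fell (0 and 6 adjusted over the list alone). Their median was -1.04 (camera adjusted p = 0.000718; adjusted p = 0.216 with an estimated correlation), with Hal (histidine ammonia-lyase) at -1.76 ± 0.30 (adjusted p = 0.00416) and Prodh (proline dehydrogenase) at -1.28 ± 0.24 (0.00615, lost with E1A scaling at -0.93 and 0.0703). Of 10 genes of fatty acid oxidation and ketogenesis, 1 rose and 3 fell (1 and 7 adjusted over the list alone). The list had a median of -0.88 (0.00199; adjusted p = 0.216 with an estimated correlation). The list's call was lost with quantile normalization (-0.42, 0.0734), and its median was -0.34 with cyclic loess and -0.45 with E1A scaling. Acadsb, a dehydrogenase of branched acyl chains, changed by -1.93 ± 0.41 (0.0115). Pdk4, a kinase that restrains glucose oxidation, changed by -1.63 ± 0.35 (0.0121), with the call lost without normal array 3 (-1.38, 0.0515) and with E1A scaling (-1.28, 0.0820). Ppargc1a, a coactivator of mitochondrial genes, rose by 1.5 ± 0.31 (0.0106, or 0.75 with normexp). With marked spots kept, 20 of 30 oxidation genes fell and 1 rose (27 and 1 adjusted over the list alone), and 8 fell with quantile normalization, 8 with cyclic loess, 3 with E1A scaling and 29 with the array median. The median stood at -1.01 (4.47e-09; adjusted p = 0.0626 with an estimated correlation), or -0.60 with quantile normalization, -0.53 with cyclic loess and -0.67 with E1A scaling. Of 28 urea cycle and amino acid genes then tested, 12 fell and 0 rose (16 and 0 adjusted over the list alone), and their median was -0.95 (1.98e-06; adjusted p = 0.136 with an estimated correlation), or -0.58 with quantile normalization, -0.49 with cyclic loess and -0.60 with E1A scaling. The 12 falls became 7, 7 and 2 under these and 21 with the array median. Without marked spots the urea cycle median was -0.69 with E1A scaling, and its 4 falls became 2 with quantile normalization, 2 with cyclic loess, 1 with E1A scaling and 6 with the array median. The 3 oxidation falls became 3, 3, 1 and 8 in this order.

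Lipid synthesis and glucose genes were lower in part. Of 7 genes of fatty acid synthesis, 0 rose and 2 fell (0 and 2 adjusted over the list alone). Their median was -0.95 (camera adjusted p = 0.0246; adjusted p = 0.418 with an estimated correlation), with Elovl5, an elongase, at -2.64 ± 0.49 (adjusted p = 0.00562). The list's call was lost without fibrosis array 2 (-0.85, 0.0846), with no filter (-0.37, 0.0504) and with the filter on all 6 arrays (-0.66, 0.0789), and the median was -0.58 with E1A scaling. Values with marked spots kept had 6 of 15 lower and 1 higher (8 and 1 adjusted over the list alone). They included Scd, a desaturase, which changed by -2.99 ± 0.56 (0.00613), while Fasn (fatty acid synthase) rose by 0.85 ± 0.26 (0.0437), a call lost with quantile normalization (0.81, 0.0534), the array median (0.50, 0.177) and no filter (0.0834) and without each array but normal array 1. Of 10 genes of cholesterol synthesis, 0 rose and 2 fell (0 and 2 adjusted over the list alone) and the list did not pass (-0.30, 0.102), its median turning to 0.02 with E1A scaling. It passed without fibrosis array 2 (-0.60, 0.0381), and its median was -0.52 with slide row as a block. Tm7sf2, a sterol reductase, changed by -2.11 ± 0.54 (0.0284, 2 unmarked normal arrays), a call lost without fibrosis array 1 (-1.74, 0.0649) or 3 (-1.95, 0.0632). When marked spots were kept, the cholesterol list had 1 of 23 higher and 3 lower (1 and 3 adjusted over the list alone). The list stood at -0.47 (0.0444; adjusted p = 0.499 with an estimated correlation), and lost its call without normal array 1 (-0.30, 0.166) or 2 (-0.40, 0.0590) and without fibrosis array 1 (-0.32, 0.138) or 3 (-0.26, 0.0597). It was also lost with quantile normalization (-0.24, 0.218), the array median (-0.83, 0.0652), cyclic loess (-0.16, 0.157), the filter on all 6 arrays (0.0659) and normexp (-0.44, 0.0513), and the median was -0.13 with E1A scaling. Of 11 genes of glucose metabolism, 0 rose and 5 fell (1 and 7 adjusted over the list alone). The list had a median of -0.74 (0.00199; adjusted p = 0.270 with an estimated correlation), with Ppp1r3c, a glycogen-targeting subunit, at -1.73 ± 0.27 (0.00239). The glucose call was lost with quantile normalization (-0.33, 0.0961) and cyclic loess (-0.25, 0.0688), and the median was -0.40 with E1A scaling. Its 5 falls became 2 with quantile normalization, 2 with cyclic loess, 1 with E1A scaling and 8 with the array median. With marked spots included, 0 of 18 rose and 8 fell (1 and 10 adjusted over the list alone), at a median of -0.72 (0.000501; adjusted p = 0.114 with an estimated correlation). That call stayed with quantile normalization (-0.34, 0.0352), cyclic loess (-0.28, 0.0256) and E1A scaling (-0.37, 0.000282), and G6pc1 (glucose-6-phosphatase) changed by -1.43 ± 0.26 (0.00570, or -0.89 with cyclic loess).

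Inflammatory cytokines and adhesion molecules were higher. Of 20 tested, 8 rose and 0 fell (10 and 1 adjusted over the list alone). The median was 1.05 (camera adjusted p = 0.00779; adjusted p = 0.216 with an estimated correlation), or 0.67 with the array median. Besides Ccl20, the monocyte chemokine Ccl7 rose by 3.70 ± 0.54 (adjusted p = 0.00190, or 2.42 with normexp). Over values that included marked spots, 9 of 23 rose and 2 fell (10 and 2 adjusted over the list alone). The 2 were the chemokine Ccl5 at -0.98 ± 0.26 (0.0263) and the interleukin Il1a at -1.74 ± 0.51 (0.0382), and both calls were lost with E1A scaling (0.267 and 0.150), cyclic loess (0.0955 and 0.0502) and no filter (0.0529 and 0.0616), as well as without some arrays. Of 5 acute phase genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), and the list did not pass (median 0.49, camera adjusted p = 0.382). It passed with quantile normalization (0.47, 0.0456) and, just under the threshold, with cyclic loess (0.56), but not with the array median (0.11, 0.336) or E1A scaling (0.85, 0.382). A2m (alpha-2-macroglobulin) rose by 3.86 ± 0.37 (0.000216) and Il1rn, an interleukin-1 antagonist, by 1.62 ± 0.34 (0.0103). Among values with marked spots kept, 5 of 21 acute phase genes rose and 2 fell (5 and 2 adjusted over the list alone), with Lcn2 (lipocalin 2) up by 4.40 ± 0.34 (8.60e-05) and Crp (C-reactive protein) at -2.13 ± 0.43 (0.00890). The median of these 21 was -0.41 and their mean 0.23, and the list did not pass (camera adjusted p = 0.764). The median turned to 0.09 with quantile normalization and 0.22 with cyclic loess, while it was -0.77 with the array median and -0.07 with E1A scaling.

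Markers of granulocytes and mast cells were higher, while the macrophage list passed only under some alternatives and the lymphocyte list did not pass. Of 11 granulocyte and mast cell markers, 6 rose and 1 fell (8 and 1 adjusted over the list alone). The median stood at 1.29 (camera adjusted p = 0.0287; adjusted p = 0.365 with an estimated correlation), with Cma1, a mast cell chymase, up by 3.36 ± 0.42 (adjusted p = 0.000909) and S100a9 of neutrophils by 2.94 ± 0.62 (0.0108). The list's call was lost without normal array 1 (1.25, 0.0997) or 3 (1.24, 0.0893), without fibrosis array 1 (1.01, 0.168) and with E1A scaling (1.64, 0.110). Of 10 macrophage markers, 3 rose and 0 fell (4 and 0 adjusted over the list alone). Together they had a median of 0.93 (0.0710). The list passed without normal array 2 (1.09, 0.0416), with quantile normalization (0.80, 0.0311), cyclic loess (0.89, 0.0292), normexp (0.79, 0.0293) and array weights (0.87, 0.0372), and its median was 0.87 with slide row as a block. It also passed at 0.93 with no filter (0.0254), the filter on all 6 arrays (0.0232) and the trend and robust settings (0.0387). It did not pass with the array median (0.54, 0.131) or E1A scaling (1.27, 0.113), nor without normal array 1 (0.85) or 3 (0.79) or fibrosis array 1 (0.19), 2 (0.45) or 3 (0.50). Itgam rose by 1.80 ± 0.44 (0.0249, 2 unmarked fibrosis arrays), a call lost without normal array 1 (1.65, 0.0711) or 3 (1.65, 0.0827) and with quantile normalization (1.30, 0.0818) or cyclic loess (1.44, 0.0613). Once marked spots were kept, 4 of 20 macrophage markers rose and 1 fell (8 and 1 adjusted over the list alone). Their median was 0.55 (0.0232; adjusted p = 0.234 with an estimated correlation), a call lost without normal array 1 (0.30, 0.0737) or fibrosis array 1 (0.35, 0.0714), and the median was 0.19 with the array median and 0.89 with E1A scaling. Of 13 lymphocyte markers, 1 rose and 1 fell (0 and 0 adjusted over the list alone). The list had a median of 0.43 (0.733). In values with marked spots kept, the lymphocyte median of 0.25 turned to -0.10 with the array median, -0.09 with quantile normalization and -0.19 with slide row as a block.

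Lists of the other cell types did not pass or were too small to test. Of 12 endothelial markers, 2 rose and 2 fell (3 and 2 adjusted over the list alone). The median stood at 0.28 (camera adjusted p = 0.658), which turned to -0.08 with the array median, with Flt1 (a VEGF receptor) up by 2.29 ± 0.32 (adjusted p = 0.00220, 2 unmarked fibrosis arrays, or 1.08 with normexp). Of 8 pancreas markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of -0.17 and a mean of 0.04 (0.658), and the median turned to 0.17 with E1A scaling and 0.11 without fibrosis array 1, while it was -0.59 with quantile normalization, -0.53 with the array median and -0.39 with cyclic loess. Of 4 blood and erythroid markers, 1 rose and 0 fell (1 and 1 adjusted over the list alone), at -0.16, which turned to 0.06 with cyclic loess and 0.19 with E1A scaling and was -0.51 with the array median. Of 3 adipocyte and mesothelial markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone), at 0.27, which turned to -0.09 with the array median and -0.06 with quantile normalization and was 0.61 with E1A scaling. The gene that rose was Msln, and the mesothelial regulator Wt1 was at -0.51 ± 0.40 (0.407), or 3.75 for its lowest probe (0.00311). With marked spots kept, the fatty acid binding protein Fabp4 rose by 3.4 ± 0.33 (0.000233).

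Of 10 antioxidant and metallothionein genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone). Together they had a median of -0.56 (camera adjusted p = 0.193), which turned to 0.04 with cyclic loess, 0.18 without normal array 1, 0.23 without normal array 3 and 0.03 without fibrosis array 3. The 1 fall without marked spots became 2 with quantile normalization, 4 with the array median and 0 with E1A scaling. Gpx2, a glutathione peroxidase of epithelia, rose by 3.70 ± 0.56 (adjusted p = 0.00213). With marked spots kept, Gclc, which makes the first step of glutathione synthesis, changed by -2.01 ± 0.25 (0.000817). When marked spots were kept, 1 of 18 rose and 6 fell (1 and 8 adjusted over the list alone). Their median was -0.50 (0.0318; adjusted p = 0.142 with an estimated correlation), a call lost without fibrosis array 3 (-0.29, 0.236), with quantile normalization (-0.27, 0.323), cyclic loess (-0.18, 0.249) and no filter (-0.30, 0.0929), and the median was -0.86 with the array median and -0.16 with E1A scaling. Of 8 genes of the unfolded protein response, 1 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of -0.10 and a mean of 0.12 (0.624), and the median turned to 0.02 with cyclic loess and 0.24 with E1A scaling.

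Cell cycle genes rose as a group. Of 22 tested, 11 rose and 0 fell (18 and 0 adjusted over the list alone), and all 22 had positive values. The rises numbered 17 with E1A scaling, 12 with cyclic loess and 11 with quantile normalization or the array median. The list's median was 1.41 (camera adjusted p = 4.37e-06, or 0.216 with an estimated correlation). The mitotic cyclins Ccnb1, at 2.67 ± 0.40 (adjusted p = 0.00329, 2 unmarked fibrosis arrays), and Ccnb2, at 2.54 ± 0.38 (0.00307, 2 unmarked fibrosis arrays), rose most. Among values with marked spots kept, 18 of 27 rose and 0 fell (24 and 0 adjusted over the list alone). The list had a median of 1.37 (1.84e-09; adjusted p = 0.114 with an estimated correlation).

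**Figure D2:**
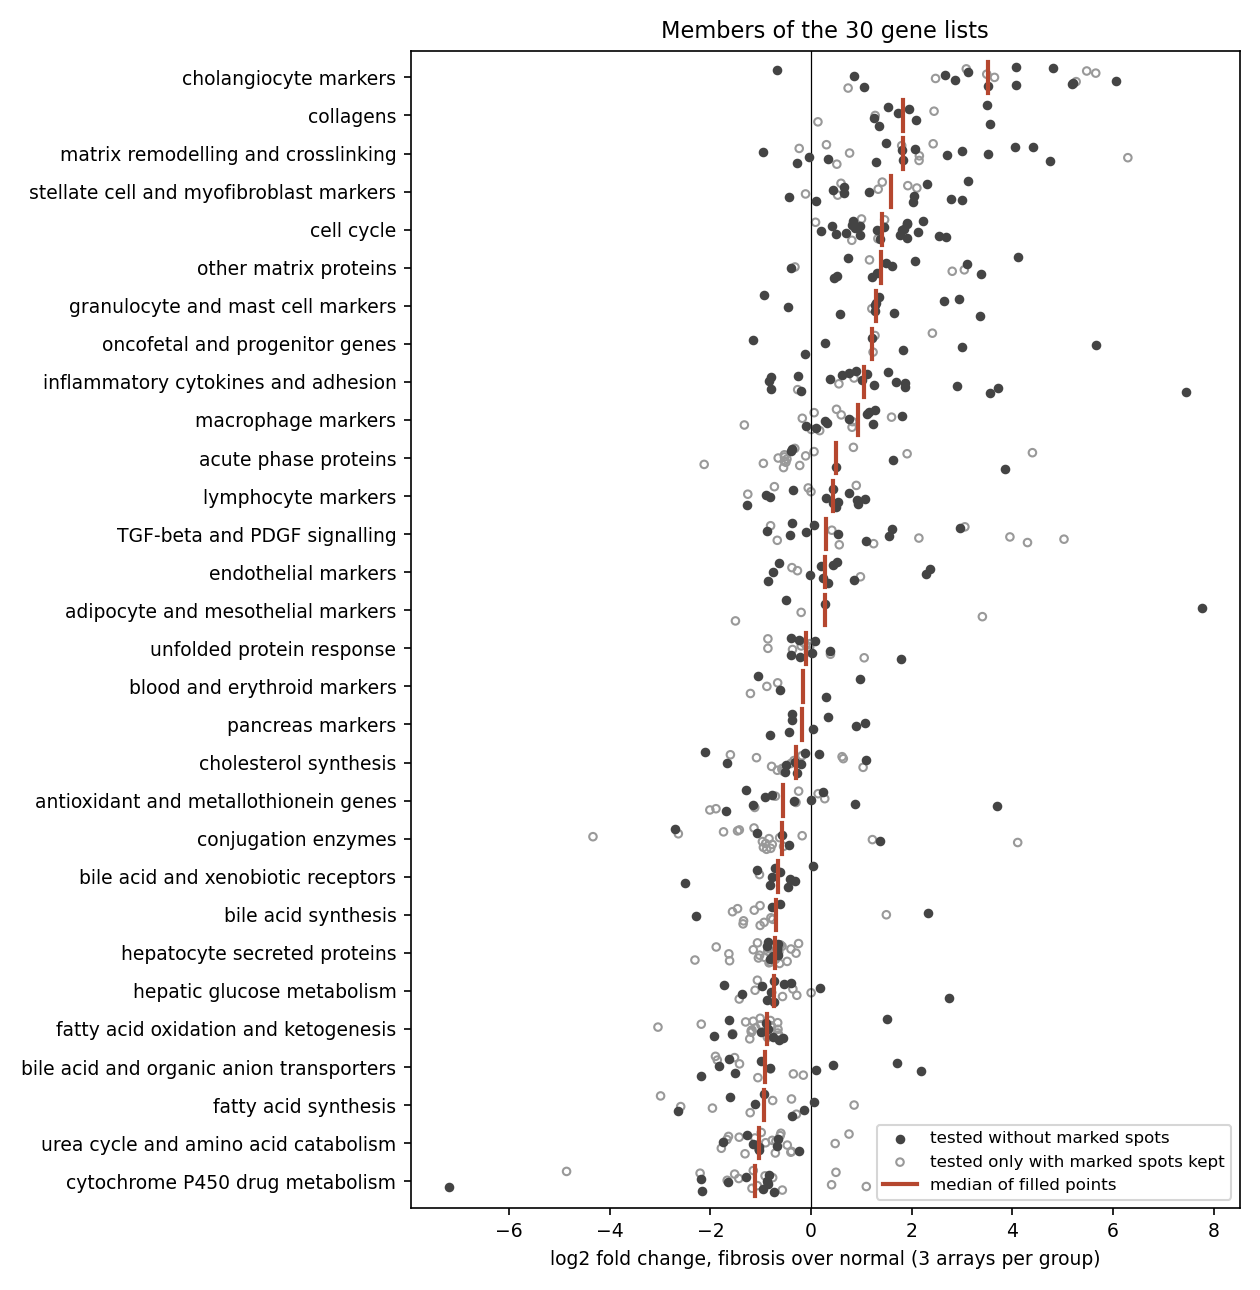
Log2 difference of each tested gene (fibrosis minus normal, horizontal axis) in each of the 30 gene lists (rows), with filled points for genes tested without marked spots, open points for genes tested only with marked spots kept and a red bar at the median of the filled points. The cholangiocyte list lies farthest to the right, at a median of 3.51, and the cytochrome P450 list farthest to the left among the lists tested, at -1.13.

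With an estimated correlation between genes, camera called 0 lists in either direction. The fry test, which does not compare a list with other genes, tested 22 lists and called 7 higher and 5 lower. Of the lists that camera called, fry could not test cytochrome P450 enzymes and fatty acid synthesis. With marked spots kept, fry gave these an adjusted p of 0.00127 and 0.00550. Over all alternatives run, the medians of the lists that did not pass without marked spots ran from -0.20 to 0.94 for TGF-beta and PDGF signalling, -1.29 to -0.36 for the transporters and -1.0 to -0.16 for conjugation enzymes. They ran from -0.41 to 0.85 for acute phase proteins, -0.67 to 0.02 for cholesterol synthesis, 0.19 to 1.27 for macrophage markers and -0.09 to 0.78 for lymphocyte markers. The others ran from -0.08 to 0.64 for endothelial markers, -0.93 to 0.23 for antioxidant genes, -0.46 to 0.24 for the unfolded protein response, -0.01 to 1.69 for oncofetal genes and -0.59 to 0.17 for pancreas markers. Of the probes without a gene symbol, 4439 were tested, of which 491 were higher and 198 lower. That is 15.5% of them, against 22.4% of the probes with a symbol. The unnamed lower probes numbered 111 without normal array 1, 88 without normal array 2 and 79 without normal array 3, and the unnamed higher ones 317 without normal array 3.

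Slide position could be set apart from group only through fibrosis array 1, which shared its slide row with the normal arrays. With slide row as a block, the group difference is that of fibrosis array 1 from the normal arrays, since fibrosis arrays 2 and 3 alone held the second row. Such values rest on 1 fibrotic liver, so only effect sizes are given. They do not show whether a result holds across the fibrotic livers. Medians were -0.99 for fatty acid synthesis, 0.87 for macrophage markers, -0.52 for cholesterol synthesis and 2.03 for granulocyte and mast cell markers. Of the lists called without the block, medians with it ran from 1.17 for inflammatory cytokines to 3.32 for cholangiocyte markers among those higher, and from -0.85 for the receptors to -1.16 for the urea cycle among those lower. Setting 1 fibrosis array against the normal arrays widens the standard error by design, so calls can end without an effect of slide row. Among the higher genes named above, calls ended for Acta2 (1.26), Col1a1 (2.62), Tgfb1 (1.5), Cyp7b1 (2.17), Ppargc1a (1.42) and Il1rn (1.74). Among the lower ones they ended for Mmd2 (-5.26), A1bg (-3.93), Nr0b2 (-2.57), Ppara (-0.98), Cyp39a1 (-1.36) and Abcb1a (-2.06). They also ended for Cyp2d3 (-1.91), Prodh (-1.34), Acadsb (-1.27), Pdk4 (-1.39), Elovl5 (-1.73) and Igf2 (-1.24). With marked spots kept, calls ended for Abcb11 (-0.80), Slc10a1 (-1.33), Apoa4 (-2.46), Pon1 (-1.43), Cyp2c12 (1.22) and G6pc1 (-1.43). The same held for Fasn (0.80), Ccl5 (-0.89), Il1a (-0.77), Crp (-1.75) and the antioxidant list (-0.60).

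Marked spots lay mostly among the bright ones. Of all spots, 28.4% ± 5.86 (SD, n = 3) on the normal arrays and 26.5% ± 7.38 (SD, n = 3) on the fibrosis arrays were marked non-uniform. In the brightest 10% the share ran from 55.9% on normal array 1 to 83.1% on normal array 2, and in the dimmest 10% it was 0 on each array. Abundant liver transcripts such as Alb were therefore measured only with marked spots kept.

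**Figure D3:**
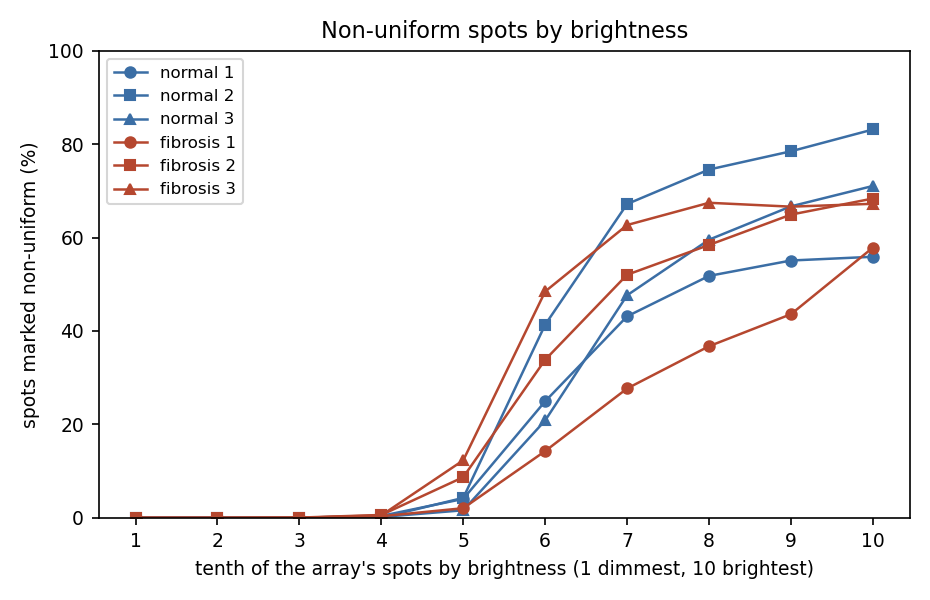
Percent of spots marked non-uniform (vertical axis) by brightness in 10 classes of equal size (horizontal axis) for each of the 6 arrays, with 1 line per array. The share is 0 in the dimmest class and between 55.9% and 83.1% in the brightest.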

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

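The offset test was chosen before its value was seen. Its further measures, the brightness test, the tests of Cyp2c11 and the cholangiocyte markers and the count of splits were chosen after the results were seen. The medians of the hepatocyte secreted, cholangiocyte and endothelial lists were known by then, so tests built on them restate known values. Values of some sex-biased genes were known too.

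A set of 773 genes was called among those that could be tested only with marked spots kept, a signal in spots that the comparisons without them do not use. Of these genes 284 were higher and 489 lower, so 63.3% were lower, against 24.1% of the genes called without marked spots. That balance was counted in the main scaling only. With marked spots kept, all higher and lower calls numbered 2011 and 227 with E1A scaling, and 1317 and 2556 with the array median. Without marked spots they numbered 1588 and 108, and 1005 and 1170. The direction of these 773 genes under other scalings was not tested, so their excess of falls may depend on the scaling. Where a probe had both kinds of spots on an array, marked spots lay above unmarked ones by 0.152 in normal and 0.177 in fibrosis, a difference of 0.0251 (SE 0.0382), and on probes of the 773 genes themselves the difference was 0.0245 (SE 0.0576). The first difference plus 2 SE comes to 0.102, just past the limit of 0.1 set for it. The smallest fall among the 489 genes was 0.685, a size in part set by their being called. A mean offset between groups was smaller than these falls. Offsets varied between probes, however, with an SD from 0.404 on normal array 1 to 0.674 on fibrosis array 1. Offsets of single probes as a cause of these falls are therefore not decided. Probes with no unmarked spot could not be tested and stay open. Genes tested without marked spots and matched on brightness had 52.7% lower calls (95% bootstrap interval 48.8 to 56.7, 1000 draws) when matched on the normal arrays, the match tried first, and 40.1% (36.5 to 44.0) when matched on all 6 arrays, so brightness may account for part of the share, and how much cannot be told apart. The draws were of genes, which are not independent, so the intervals do not measure variation between animals.

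Cyp2c11, an enzyme typical of male rat liver, fell 147-fold. With marked spots kept, 7 of 8 other male-biased genes fell, at a median of -1.20. The 9 female-biased genes had a median of -2.01 with 1 higher (Cyp2c12) and 6 lower. The falls of the female-biased genes argue against rats of the other sex or a wrong label as the whole cause. The falls of the male-biased genes and the rise of Cyp2c12 go with that explanation. Values of Prlr, A1bg, Cyp3a9 and Cyp2c12 had been seen before this test was chosen, so it is not independent of them. Secreted proteins of hepatocytes, also with marked spots kept, had a median of -0.78, far less than Cyp2c11. That argues against a lower share of hepatocytes as the whole cause. A response to bile duct ligation was not tested and stays open, and slide row was only in part separable from group.

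Markers of cholangiocytes rose more than those of other cell types than hepatocytes. Their mean shift exceeded that of endothelial markers by 2.82 on the fibrosis array with the smallest gap, and the gaps given here are with marked spots kept. A lower share of hepatocytes alone would raise both alike. Of the endothelial markers 3 were higher and 2 lower, so their list is not a neutral gauge of that share. The gap to stellate cell markers was at least 2.04 and that to granulocyte and mast cell markers at least 1.36. The difference of the cholangiocyte and endothelial medians, also with marked spots kept, was 3.31 under cyclic loess. That was the lower of cyclic loess and quantile normalization, so neither of them removed the gap. Scalings that subtract 1 value per array cannot change it. More bile duct cells and higher expression in each cell may both lie behind the rise, and neither was tested.

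The comparison called 1781 genes, and 1 of 10 splits of the 6 arrays into 3 and 3 gave as many, the real one, while limma called at most 0 in the others. The splits are too few for a share under 0.05.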

How the results depend on the processing

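Normexp, E1A scaling, slide row as a block, marked spots kept with quantile normalization and every alternative on values with marked spots kept were chosen after seeing the data; the others were chosen before. The arrays' signal over background limits what dim genes show, and 3 arrays per group limit precision. Of 106 named genes 100 were called, and 53 of these kept their call and direction under all alternatives that tested them. That held for 0 of 15 called lists, since the setting with an estimated correlation ended each call. With marked spots kept it held for 25 of 55 called genes. There 20 of 23 called lists kept their call under the alternatives other than an estimated correlation. That setting ended all 23 (lowest camera adjusted p = 0.0626). It also tests with far fewer degrees of freedom, so correlation between genes need not be what ended a call. Genes that remodel or crosslink matrix had an estimated correlation of 0, yet camera's unadjusted p went from 2.52e-05 to 0.0108. Genes that an alternative did not test count as kept there, and the filter on all 6 arrays tested 69 of the 106. E1A scaling ended calls of 19 of the 106 genes, no filter of 16 and quantile normalization of 14, and the cause was not tested. Slide row as a block also ended calls. It sets fibrosis array 1 alone against the normal arrays, which widens the standard error, so lost calls there need no effect of slide row. The counts of kept calls above include that fit. Leaving out normal array 3 ended calls of 22 of 93 genes, normal array 2 of 20 of 104, normal array 1 of 14 of 93 and fibrosis array 1 of 15 of 85 besides Tgfb2, which turned below 0 there and lost its call too. Tgfb2 turned from 2.95 to -0.62 for its lowest probe, and ranged from -0.58 without fibrosis array 1, with -0.57 without fibrosis array 3, to 3.21 without normal array 2. Wt1 turned from -0.51 to 3.75 for its lowest probe, a choice of another probe.

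Counts moved by more than 1.5 times as follows, in the order genes lower, genes lower at least 2-fold and lower probes without a symbol, against 429, 338 and 198. They were 677, 572 and 438 with quantile normalization (with 4 lists lower against 7), 1170, 916 and 570 with the array median, 991, 688 and 351 with marked spots kept (with 12 lists lower), 1035, 846 and 541 with marked spots kept and quantile normalization, and 108, 106 and 57 with E1A scaling. With no filter 249 genes and 115 unnamed probes were lower, and with array weights 899 and 420. With the filter on all 6 arrays, 826 genes were higher at least 2-fold and 264 unnamed probes were higher and 124 lower, since fewer genes were tested. With an adjusted p under 0.01, 794 genes were higher and 106 lower, all at least 2-fold (794 and 106), and 262 and 49 unnamed probes. Testing against a log2 change of 0.5 gave 847 and 131 genes, all at least 2-fold (847 and 131), and 305 and 58 unnamed probes. These 2 thresholds are stricter by construction. With slide row as a block, 749 genes were higher and 97 lower, all at least 2-fold (749 and 97), and 232 and 40 unnamed probes. With an estimated correlation camera called 0 lists higher and 0 lower, while fry called 7 and 5 of the 22 lists it tested. Where no cause is given, the cause was not tested.

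Leaving out 1 array in turn gave 889 to 1493 genes higher and 142 to 525 lower, 889 to 1394 and 142 to 380 at least 2-fold, 317 to 571 unnamed probes higher and 79 to 217 lower, and 6 to 9 lists higher and 6 to 8 lower. Normexp on mean signals was not run because the files hold no such column, and a block for slide or scan because there was 1 of each. No paired analysis was possible because the array numbers only follow the order of the records.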

Other observations

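These 10 further gene lists were chosen after the main results were seen and before their own list values. All 10 are given here with marked spots kept, and at the end without them. Some of their members had been seen in the first 30 lists or named above. Krt7, Krt19, Cldn4, Cldn7, Cftr, Aqp1 and Slc4a2 are also cholangiocyte markers, and Cldn9 was a top increase. The keratin, claudin and apical channel lists therefore partly repeat earlier results.

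Keratins, which form the filaments of epithelial cells, were higher, 6 of 9 called and 0 lower (6 and 0 adjusted over the list alone), at a median of 2.43 (camera adjusted p = 0.000917; adjusted p = 0.149 with an estimated correlation). Claudins and tight junction genes had 7 of 19 higher and 4 lower (8 and 4 adjusted over the list alone), at 0.67, or 0.32 with the array median and 1.02 with E1A scaling (0.00605; adjusted p = 0.149 with an estimated correlation). There were 5 of 16 epithelial apical channels higher and 0 lower (8 and 0 adjusted over the list alone), at 0.75, or 0.40 with the array median (0.00294; adjusted p = 0.149 with an estimated correlation). Notch, Hedgehog and Wnt genes had 8 of 21 higher and 0 lower (8 and 1 adjusted over the list alone), at 0.46 (0.0247; adjusted p = 0.149 with an estimated correlation). That median was 0.05 with quantile normalization, 0.11 with the array median, 0.19 with cyclic loess and 0.81 with E1A scaling.

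The mitochondrial respiratory chain stood at -0.58 over 31 genes (camera adjusted p = 4.27e-05; adjusted p = 0.149 with an estimated correlation), with 0 higher and 2 lower (0 and 0 adjusted over the list alone). That median was -0.21 with quantile normalization, -0.14 with cyclic loess, -0.24 with E1A scaling and -0.94 with the array median. Circadian clock genes had 1 of 15 higher and 4 lower (2 and 4 adjusted over the list alone), at -0.68 (0.0422; adjusted p = 0.299 with an estimated correlation), or -1.04 with the array median and -0.34 with E1A scaling. Ribosomal proteins had 0 of 47 higher and 0 lower (0 and 0 adjusted over the list alone) by limma, at -0.27 (0.0247; adjusted p = 0.641 with an estimated correlation), which turned to 0.16 with quantile normalization, 0.25 with cyclic loess and 0.07 with E1A scaling.

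The other lists did not pass. Interferon-stimulated genes stood at 0.44 over 23 genes (camera adjusted p = 0.0919), with 3 higher and 0 lower (3 and 0 adjusted over the list alone), and at 0.09 with the array median and 0.79 with E1A scaling. Complement and coagulation regulators stood at -0.28 over 27 genes (0.166), with 2 higher and 3 lower (2 and 3 adjusted over the list alone), which turned to 0.09 with quantile normalization, 0.16 with cyclic loess and 0.07 with E1A scaling. The growth hormone and IGF axis stood at -0.01 over 18 genes (0.729), with 1 higher and 2 lower (1 and 2 adjusted over the list alone), and its sign turned with quantile normalization, cyclic loess and E1A scaling.

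Without marked spots fewer genes were tested, and the calls of keratins and of Notch, Hedgehog and Wnt genes depended on keeping such spots. Keratins then had 3 of 6 higher and 0 lower (3 and 0 adjusted over the list alone) at a median of 1.42, which did not pass (camera adjusted p = 0.106), and Notch, Hedgehog and Wnt genes had 6 of 17 higher and 0 lower (6 and 1 adjusted over the list alone) at 0.14 (0.111). Claudins and tight junction genes stood at 1.03 over 14 genes (0.00931), with 6 higher and 2 lower (7 and 2 adjusted over the list alone), and apical channels at 0.83 over 12 (0.00949), with 5 and 0 (6 and 0). The respiratory chain stood at -0.57 over 15 genes (0.00143), with 0 higher and 0 lower (0 and 0 adjusted over the list alone) by limma. Circadian clock genes stood at -0.83 over 13 (0.00500), with 0 and 4 (1 and 5), and ribosomal proteins at -0.30 over 18 (0.0319), with 0 and 1 (0 and 0). With an estimated correlation the adjusted p was at least 0.301 for each of these lists. Interferon-stimulated genes at 0.40 over 15 (0.239), complement and coagulation regulators at -0.14 over 9 (0.802) and the growth hormone and IGF axis at 0.41 over 14 (0.580) did not pass.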
